A study of Mus musculus with 9 samples.

How the data were processed

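The authors hybridised biotin-labelled cDNA from total RNA of 9 mouse skeletal muscles to GeneChip whole-transcript arrays, 1 array per muscle, per the labels' protocols. Whether RNA of several animals was pooled is not given in the sources used here. The deposited values are log2 expression values per probe set, and GCRMA, which corrects background by probe sequence and normalizes between arrays, is named in the submitters' processing notes without a version. The log2 scale was read from the values, which ran from 0.12 to 13.49 with medians from 3.34 to 3.44 per array. The sorted values of the arrays differed by up to 0.39, so that the columns were close to, and not exactly, of equal distribution. No detection calls were used, and low values cannot be told from background. This bears on most Hox genes.

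The table held 41345 probe sets. The gene table for the array named genes for 25335 of them, 23521 with 1 gene and 1814 with several, and 16010 had no gene named here. Symbols were updated through Entrez identifiers to the GRCm38.p6 gene table, which matched 23328 of the probe sets with 1 gene and left 193 under the symbol of the array table. No genome build is named for the array, so no coordinates are given. For each of the 1082 genes with more than 1 probe set the one with the highest mean over the 9 arrays was used, which left 22180 genes. Probe sets without a gene or with several genes were tested apart.

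The head group had 2 arrays, the shoulder and forelimb group 3 and the hindlimb group 4. All 9 arrays entered 1 fit with a mean per group in limma 3.58.1 (R 4.3.3), with lmFit and eBayes without trend or robust settings, and 3 two-sided contrasts. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The fit had 6 residual degrees of freedom, and 10.4 after moderation. Every adjusted p of a gene comes from limma, and from this fit unless another setting is named beside it. Calls adjusted over a list alone used the p-values of this fit. They were not corrected for the number of lists, 28 in each comparison, so that some can be expected by chance. An exact permutation test of a single value, with the p of the smaller tail doubled, could not go below 0.133 for hindlimb against head muscles. Its floor was 0.0571 for hindlimb against shoulder and forelimb, and 0.2 for shoulder and forelimb against head muscles. Other forms of the test can have a lower floor.

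Gene lists for Hox genes, patterning factors, fibre types, metabolism, connective tissue, stress and clock genes, and markers of other cell types were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Of 29 lists, 28 had at least 3 measured genes. The list of erythroid markers had fewer and was not tested. Of 410 list entries 42 were not measured by a probe set of a single gene. A listed symbol was replaced by its current one only where neither the gene table nor the array table used it, which held for 1 entry (Cyr61, now Ccn1). This order of matching was set after values had been seen, so that Muc19 stayed in the salivary list.

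Per comparison, named genes were the 10 with the largest change in each direction among those past the threshold, or all if fewer. Where under 5 passed, those with the largest moderated statistic filled up to 5 and are given as not passing. All Hox genes and any list member could be named, and for each muscle the 5 genes that exceeded the other arrays by most. Predicted genes, microRNAs and similar symbols were not named. With the exceptions below, the groups, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined. Set afterwards were the alternatives on the value range of the arrays and the order of symbol matching. Some tests of explanations, named in the closing sections, were also chosen afterwards.

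The procedure was tested on simulated data for 22180 genes with 200 changed. A log2 change of 2 was recovered for 89.7% of changed genes in hindlimb against head and 93.2% in hindlimb against shoulder and forelimb muscles. It was recovered for 88.1% in shoulder and forelimb against head muscles. A change of 1 was recovered for 45%, 58.1% and 37.3% in the same order. False calls numbered 7.5, 8.1 and 7.2 on average per round. The simulated noise was independent between genes, without the value range split of the real arrays. These shares hold for that setting and do not give the power of this design. The alternatives were median centring, quantile and cyclic loess normalization, a filter on dim genes, the average of a gene's probe sets, variance trend with a robust fit, only the arrays of the groups compared, the trapezius counted with the head muscles, a slow fibre score as a covariate, each array left out in turn, the value range of the arrays as a term, and only the 6 arrays of wider range.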

Results

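Gene expression was measured in 9 skeletal muscles of male C57BL/6J mice aged 12 weeks, an inbred laboratory strain. RNA from frozen muscle was hybridised to whole-transcript GeneChip arrays, with 1 array per muscle. The title of the series concerns positional memory, the idea that adult muscles keep a molecular record of where in the body they lie, and names the homeobox gene Hoxa10. The arrays were therefore grouped by the position of the labelled muscle. The head group held the masseter and the digastric (n = 2), the shoulder and forelimb group the trapezius, supraspinatus and triceps (n = 3), and the hindlimb group the rectus femoris, tibialis anterior, soleus and gastrocnemius (n = 4). The grouping rests on general anatomy, since the labels name the muscle only. Each SD below is a spread between arrays of different muscles of a region, and the p-values rest on that spread. With 1 array per muscle, differences between muscles, between animals and between arrays cannot be told apart in it. The spread between animals for 1 muscle was not measured. The number of arrays limits the precision of every comparison.

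The arrays did not all have the same spread of values. The SD over probe sets was 1.957 in triceps, 1.951 in rectus femoris and 1.919 in gastrocnemius, and from 2.033 to 2.077 in the other 6 arrays. The first principal component, with 41.7% of the variance, parted these 3 arrays from the 6 others. None of the 3 came from a head muscle. Differences among the 6 arrays of wider range, 2 per region, are therefore given beside the called gene groups below.

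The first question was how hindlimb muscles differed from head muscles. The clearest difference was in Hoxc10, a homeobox gene of the posterior part of the Hoxc cluster. Its log2 level was 7.18 ± 0.45 (SD, n = 4) in hindlimb muscles and 3.18 ± 0.17 (SD, n = 2) in head muscles, a 16.0-fold difference in the deposited values. The head values lie near the array median, where signal cannot be told from background and differences can be compressed. Signal from the close relatives Hoxa10 and Hoxd10, which stays open below, would instead raise the fold. The fold is therefore an estimate and no bound. Hox genes of paralogue groups 5 to 8 and 9 to 13 were called higher in hindlimb muscles as groups, by mean log2 differences of 0.82 and 0.84 (adjusted p = 0.143 for both with an estimated correlation). Nr4a1, an orphan nuclear receptor induced early after stimulation, was 2.88-fold higher. Genes of the respiratory chain, of fatty acid use and of the endothelium were called lower as groups (adjusted p = 0.502 for each with an estimated correlation), with smaller differences of -0.18, -0.13 and -0.08 among the arrays of wider range.

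Of 22180 genes, 2 passed the limma test as higher in hindlimb than in head muscles and 0 as lower. Without masseter 0 passed, and without soleus 11 passed as higher and 8 as lower. At an unadjusted p under 0.05 there were 1208 higher and 1439 lower genes, where chance gives 1109 in all on average. Genes are correlated across these arrays, so that a count by chance can lie far from 1109, here and below. Hoxc10 differed by 4.0 on the log2 scale (SE 0.31, 95% interval 3.3 to 4.7, adjusted p = 0.00249), with each of the 4 hindlimb arrays above both head arrays. Without the masseter array the Hoxc10 difference was 3.88 and the adjusted p was 0.119. Among the arrays of wider range it was 4.28. Nr4a1 differed by 1.52 (SE 0.18, adjusted p = 0.0484), from 7.37 ± 0.15 (SD, n = 2) in head to 8.89 ± 0.15 (SD, n = 4) in hindlimb muscles. The Nr4a1 call held under 5 of 20 alternative settings, with adjusted p from 0.0159 to 0.429.

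The next genes by the moderated statistic did not pass. Hoxc8 was 1.14 higher (adjusted p = 0.198) and Cks1brt 0.86 higher (adjusted p = 0.206). Car3, a carbonic anhydrase abundant in slow muscle and adipocytes, was 3.62 higher (SE 0.63, adjusted p = 0.219). On the other side, Mss51, a mitochondrial protein gene of skeletal muscle, was at 11.12 in masseter and 8.16 in digastric, against 4.64 ± 0.41 (SD, n = 4) in hindlimb muscles, a log2 difference of -5.0 (SE 0.67, adjusted p = 0.0953). The interferon-induced gene Rsad2 differed by -1.23 (adjusted p = 0.0953). The potassium channel gene Kcnq5 differed by -1.46 (adjusted p = 0.158) on 1 of its 2 probe sets and by -0.27 on the other, with -0.86 for their average. Further values were Gca at -1.23 and the mitochondrial iron importer gene Slc25a37 at -1.14 (adjusted p = 0.198 for both).

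Hox genes encode transcription factors that set position along the body axis. In groups 5 to 8, all 11 measured genes had positive differences and 0 passed over all genes, while 7 passed when adjusted over the list alone, among them Hoxc6 (1.72), Hoxc8 (1.14) and Hoxa7 (1.11). In groups 9 to 13, all 15 measured genes had positive differences. There, Hoxc10 passed over all genes and 6 genes passed when adjusted over the list alone, with Hoxc9 at 1.25, Hoxc11 at 1.10 and Hoxa10 at 0.88. The camera test with its preset correlation called both groups (adjusted p = 1.9e-08 and 3.12e-08), and neither was called with an estimated correlation (adjusted p = 0.143 for both). The median of groups 9 to 13 was 0.54, and their mean ran from 0.71 to 2.05 over 22 alternative settings. The upper end came with the filter on dim genes, which drops members below the median gene, so that Hoxc10 weighs more. It is no value of the whole list. Among the arrays of wider range the mean differences were 0.72 and 0.74. In groups 1 to 4, 8 of 10 genes had positive differences, with a mean of 0.20 and no call by camera (adjusted p = 0.0954). This mean was 0.09 among the arrays of wider range, 0.10 without masseter and 0.30 without digastric. Hoxa10, the gene of the series title, was at 3.26 in both head arrays and at 4.14 ± 0.22 (SD, n = 4) in hindlimb muscles, and did not pass over all genes (difference 0.88, SE 0.23, adjusted p = 0.355).

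**Figure D1:**
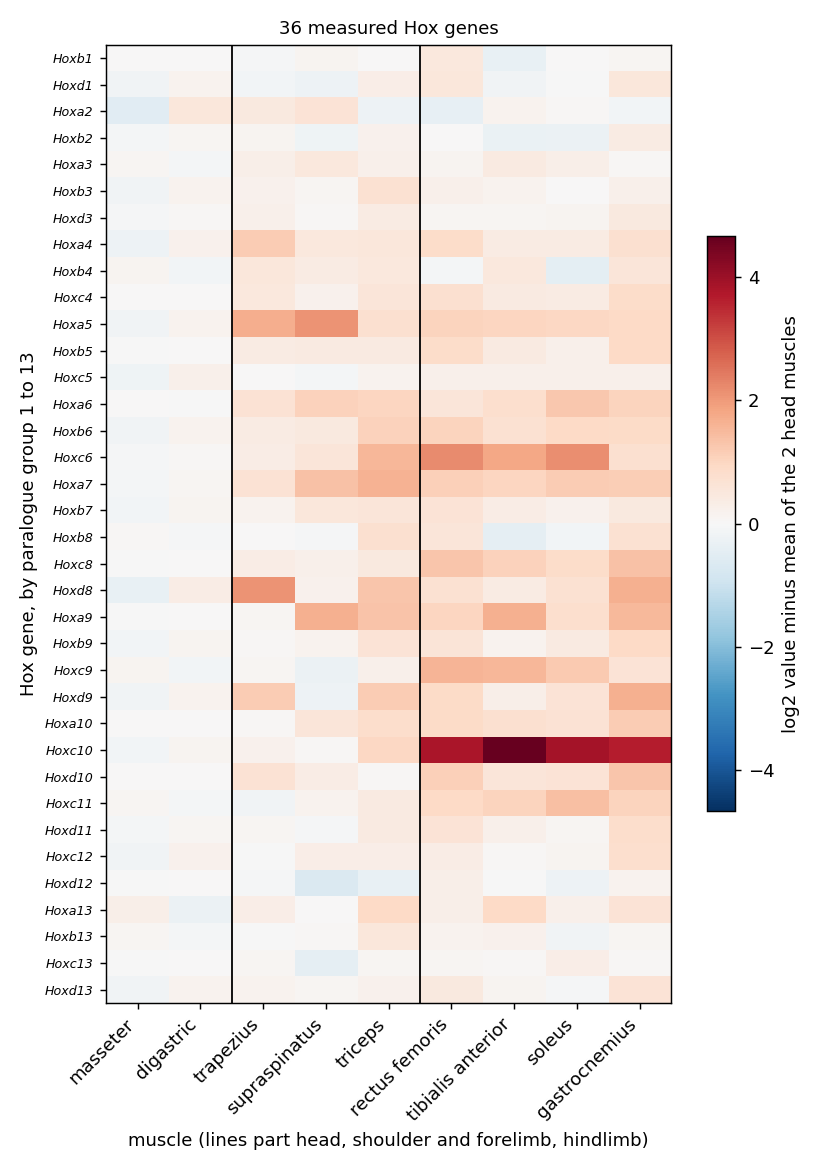
Each row is a Hox gene, ordered by paralogue group, and each column is a muscle with 1 array; colour gives the log2 value minus the mean of the 2 head muscles. Hoxc10 in the 4 hindlimb muscles stands out, at values from 6.85 to 7.84 against 3.06 and 3.3 in the head muscles.

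Every hindlimb array lay above every head array for 22 of the 36 measured Hox genes, with 3 of 10 in groups 1 to 4, 10 of 11 in groups 5 to 8 and 9 of 15 in groups 9 to 13. The share over all genes was 11.4%, and chance gives 6.7%. Many of these Hox values lay near the median of all probe sets on an array (3.34 to 3.44), and low values cannot be told from background on these arrays.

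Myogenic regulators and satellite cell markers were called higher as a group in hindlimb muscles (15 of 18 positive, mean 0.27, adjusted p = 0.0172; adjusted p = 0.184 with an estimated correlation). Among them, Pax7, the marker of muscle stem cells, differed by 0.62 and Myog, a differentiation factor, by 0.73, and 0 of the 18 passed on their own. Immediate early and handling stress genes were also called (mean 0.34, adjusted p = 0.00279; adjusted p = 0.143 with an estimated correlation), with 1 of 19 past the threshold over all genes, Nr4a1, and 2 when adjusted over the list alone, Nr4a1 and Egr2 (0.75). Fry, which tests whether the genes of a list move one way, called 4 lists, namely both Hox groups, the myogenic list (adjusted p = 0.0314) and the immediate early list (adjusted p = 0.00687). Among the arrays of wider range the myogenic and immediate early differences were 0.25 and 0.42. The list of head muscle and cranial patterning factors was called higher in hindlimb muscles (mean 0.16, adjusted p = 0.0172; adjusted p = 0.516 with an estimated correlation). Of its 18 members 15 were positive and 0 passed, and the 3 negative ones included Tbx1, a pharyngeal mesoderm factor (-0.92), and Six2 (-0.65). The list difference was -0.05 among the arrays of wider range, 0.06 without rectus femoris and 0.27 without soleus.

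Genes of the respiratory chain and citrate cycle and of fatty acid use were called lower in hindlimb muscles (adjusted p = 0.502 for both with an estimated correlation). All 23 measured genes of the former had negative differences (mean -0.48, adjusted p = 1.28e-08), with Ndufs1 at -0.87 and Cycs at -0.74 (-1.43 to -0.67 over its 5 probe sets), and so had all 17 of the latter (mean -0.52, adjusted p = 0.000279), with Lpl at -0.98 and Cd36 at -0.88. Among the arrays of wider range the mean differences were -0.18 and -0.13, and with 1 array left out the fatty acid difference ran from -0.83 (without masseter) to -0.20 (without digastric). Of these genes 0 passed over all genes, and Ucp3 (-0.74) passed when adjusted over the fatty acid list alone. The 2 probe sets of Fabp3 disagreed in sign. Endothelial markers moved with them, with 10 of 10 negative (mean -0.55, adjusted p = 0.000762; adjusted p = 0.502 with an estimated correlation), and at -0.08 among the arrays of wider range. Slow fibre genes were called higher (mean 1.27, adjusted p = 0.0388; adjusted p = 0.625 with an estimated correlation), with the list mean at 9.62 in soleus and from 4.95 to 6.33 in the other hindlimb arrays. Without soleus the slow fibre difference was 0.26, and among the arrays of wider range, soleus included, it was 2.21, and 13 of 22 alternative settings kept the call. Fast fibre genes had a mean difference of -0.05 and no call, while Myh1, the IIx myosin heavy chain gene, differed by -1.22 and Ampd1 by 1.06, both past the threshold when adjusted over the list alone.

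Connective tissue and fat markers were called higher. Extracellular matrix genes had 16 of 17 positive differences (mean 0.55, adjusted p = 1.58e-05; adjusted p = 0.502 with an estimated correlation), with Col1a1 at 1.01 and Col6a3 at 0.97, a mean of 0.55 among the arrays of wider range and of 0.33 without masseter. Tendon markers differed by a mean of 0.70 (adjusted p = 0.0307) and white adipocyte markers by 0.91 (adjusted p = 0.0313), with an adjusted p of 0.516 for both with an estimated correlation. These differences were 0.95 and 0.89 among the arrays of wider range. The tendon difference was 1.58 without digastric and -0.18 without the masseter array, whose tendon mean was 4.52 against 6.27 in digastric. The white adipocyte difference was led by Car3. When the trapezius was counted with the head muscles it was -0.11.

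The other lists were not called in this comparison. Their mean differences were 0.19 for limb patterning factors, 0.24 for developmental fibre genes, 0.03 for glycolysis, -0.10 for the neuromuscular junction, -0.11 for atrophy genes, 0.10 for clock genes, 0.22 for Schwann cell, -0.38 for salivary gland, 0.11 for keratinocyte, 0.20 for lymphocyte, 0.17 for myeloid, 0.01 for smooth muscle and 0.38 for cartilage and bone markers. With 1 head array left out, salivary gland markers ran from -0.60 to -0.17 and cartilage and bone markers from 0.16 to 0.59. Myeloid markers then ran from -0.22 to 0.57 and limb patterning factors from 0.04 to 0.34. Clock genes ran from -0.05 to 0.25, neuromuscular junction genes from -0.22 to 0.03 and glycolysis genes from -0.09 to 0.14. Brown adipocyte markers had a mean of -0.01 while their test pointed up, without a call. Within these lists, Lbx1, which marks migrating limb muscle precursors, differed by 1.91, Tbx15 by -1.35, the embryonic sarcomere genes Myh3 and Tnnt2 by 0.86 and 1.41, Per1 by 0.73, Cd79b by 0.73 and the salivary secretory gene Bpifa2 by -1.94, each past the threshold only when adjusted over its list alone. Salivary Klk1 was at 7.28 in masseter and at most 1.93 elsewhere, and Bpifa2 was at 5.16 in digastric, 3.74 in masseter and at most 2.99 elsewhere.

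**Figure D2:**
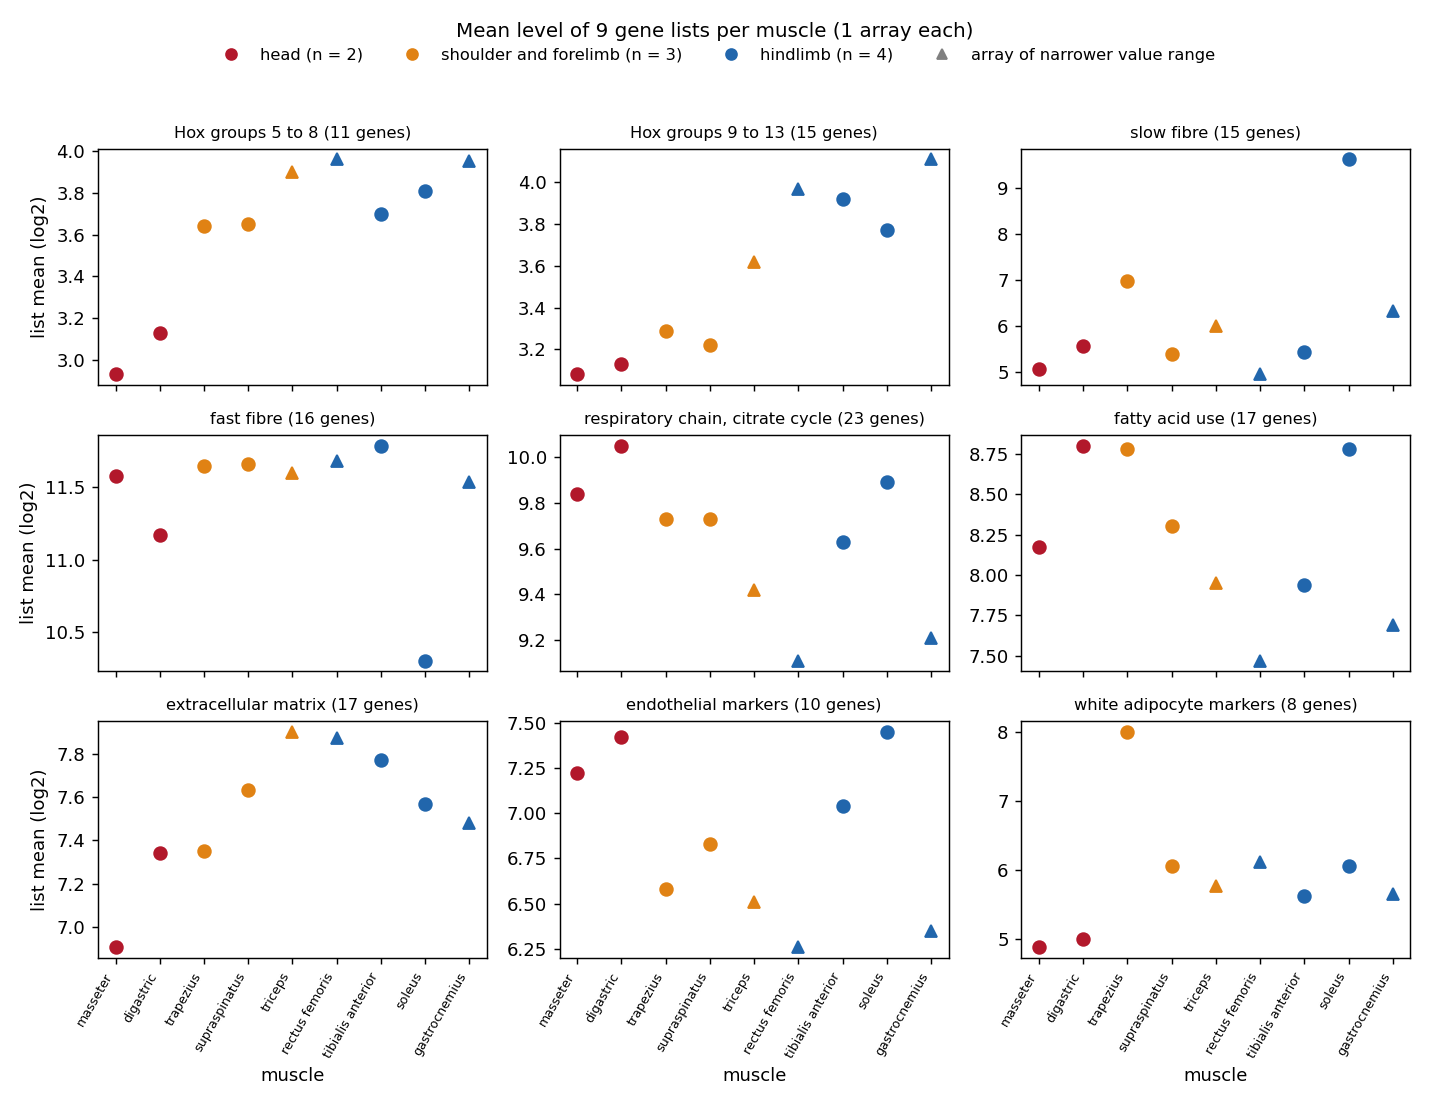
Each point is the mean log2 level of the genes of 1 list in 1 muscle, coloured by region, with triangles for the 3 arrays of narrower value range. The head muscles lie lowest for both Hox lists, soleus stands apart for slow fibre genes at 9.62 and fast fibre genes at 10.30, and trapezius for white adipocyte markers at 8.0.

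The comparison of hindlimb with shoulder and forelimb muscles asked which genes set these 2 regions apart. Hoxc10 was again the clearest difference, 12.1-fold, which is likewise an estimate and no bound. Hoxc10 was at 7.18 ± 0.45 (SD, n = 4) in hindlimb muscles against 3.58 ± 0.49 (SD, n = 3). Its Hoxc neighbours Hoxc9 and Hoxc11 were at 4.61 ± 0.44 and 4.15 ± 0.21 in hindlimb muscles (SD, n = 4), against 3.37 ± 0.25 and 3.19 ± 0.30 (SD, n = 3). Hoxa10 was at 4.14 ± 0.22 (SD, n = 4) against 3.73 ± 0.39 (SD, n = 3), a difference of 0.41 that did not pass (adjusted p = 1). Tendon markers were called higher and adipocyte, myeloid and fatty acid genes lower, as groups (adjusted p = 0.602 for each with an estimated correlation).

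In the limma test 1 gene, Hoxc10, was higher in hindlimb muscles and 0 were lower. At an unadjusted p under 0.05, 408 were higher and 402 lower, fewer in all than the 1109 of chance. The Hoxc10 difference was 3.60 (SE 0.28, 95% interval 2.98 to 4.21, adjusted p = 0.00206), with the 4 hindlimb arrays, from 6.85 to 7.84, above the highest shoulder and forelimb array, triceps at 4.14. It was 4.15 among the arrays of wider range and 2.77 between the 3 of narrower range. The adjusted p lay between 0.000652 and 0.0345 over 20 alternative settings. Other leading genes did not pass, each at an adjusted p of 1. They were Hoxc9 (1.24), Hoxc11 (0.95), Smarcd1 (0.81, or 0.32 on its other probe set) and Hoxc8 (0.80) on the higher side, and the secreted glutathione peroxidase gene Gpx3 (-1.35), Smok4a (-1.17), the glutamine synthetase gene Glul (-0.98), Alg8 (-0.70) and Mmrn1 (-0.69) on the lower side.

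**Figure D3:**
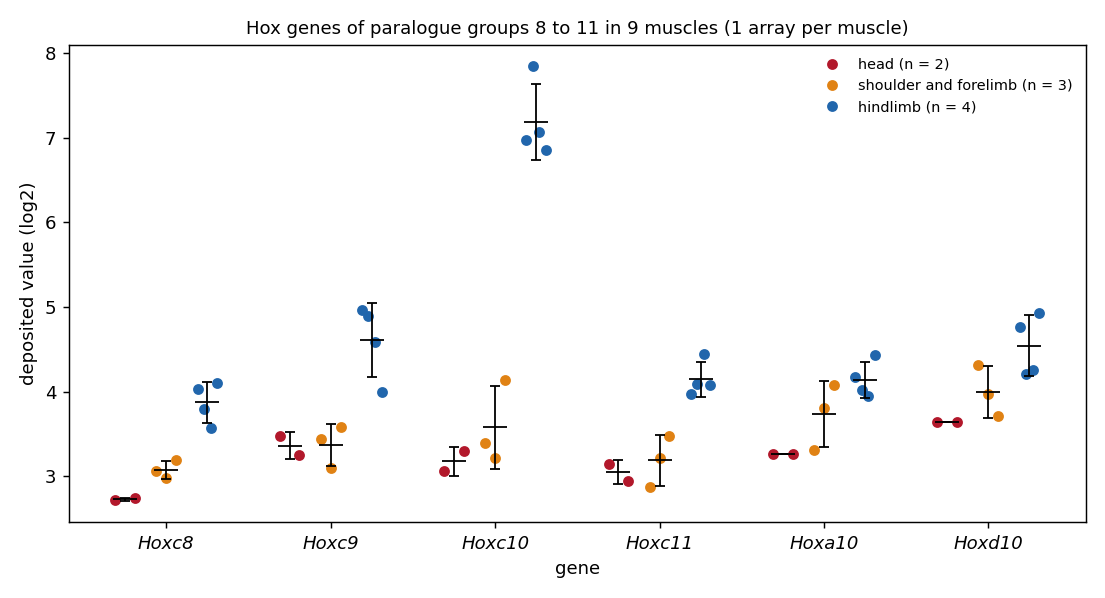
Points are the log2 values of single muscles, 1 array each, in head (n = 2), shoulder and forelimb (n = 3) and hindlimb (n = 4) groups, and the black marks are the group mean ± SD. Hoxc10 is at 7.18 ± 0.45 in hindlimb muscles against 3.58 ± 0.49 in shoulder and forelimb muscles.

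Hox groups 9 to 13 were called as higher in hindlimb muscles (14 of 15 positive, mean 0.57, adjusted p = 6.5e-09; adjusted p = 0.16 with an estimated correlation). Hoxc9, Hoxc10 and Hoxc11 passed when adjusted over the list alone. Hoxc10 raised the mean, and the median was 0.25. Over 22 alternative settings the mean ran from 0.49 to 1.79, the upper end again with the filter on dim genes, which leaves fewer members. The mean difference was 0.59 among the arrays of wider range and 0.42 between those of narrower range. Hox groups 5 to 8 had a mean of 0.12 and no call, with Hoxc8 alone past the threshold when adjusted over the list alone, and Hox groups 1 to 4 a mean of -0.08 and no call. Every hindlimb array lay above every shoulder and forelimb array for 5 of 36 Hox genes, which were Hoxc5, Hoxc8, Hoxc9, Hoxc10 and Hoxc11, all of the Hoxc cluster. The share over all genes was 2.3%, and chance gives 2.9%. The limb identity factors Pitx1, Tbx4 and Tbx5 differed by -0.02, 0.26 and -0.16, and 0 of 16 limb patterning factors passed. The list of these factors had a mean of -0.09 and no call.

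Tendon markers were called higher in hindlimb muscles (10 of 10 positive, mean 0.82, adjusted p = 2.65e-05; adjusted p = 0.602 with an estimated correlation), with Chad at 1.82 and Fmod at 1.20 (0.76 on its other probe set). The difference was 1.32 among the arrays of wider range and 0.06 between those of narrower range, and it was 0.34 without trapezius, which had the lowest tendon mean, 4.33. Myogenic genes (mean 0.11, adjusted p = 0.0334; adjusted p = 0.352 with an estimated correlation) and immediate early genes (mean 0.19, adjusted p = 0.00518; adjusted p = 0.16 with an estimated correlation) were called higher, with differences of 0.11 and 0.24 among the arrays of wider range and 0.09 and 0.16 between those of narrower range. The myogenic call was kept in 11 of 22 alternative settings. Fatty acid genes, with 17 of 17 negative (mean -0.37, adjusted p = 0.00016; adjusted p = 0.602 with an estimated correlation), were called lower, and so were respiratory chain and citrate cycle genes (mean -0.16, adjusted p = 0.00275; adjusted p = 0.68 with an estimated correlation). The 2 differences were -0.18 and 0.03 among the arrays of wider range, and between those of narrower range -0.37 and -0.26. With 1 array left out, the fatty acid difference ran from -0.64 (without soleus) to -0.16 (without trapezius) and the respiratory chain difference from -0.31 (without soleus) to -0.05 (without rectus femoris), and the latter call was kept in 12 of 22 alternative settings. Fast fibre genes were called lower (mean -0.31, adjusted p = 0.0297; adjusted p = 0.68 with an estimated correlation). Without the soleus array, whose fast fibre mean was 10.30 against 11.54 to 11.79 in the other hindlimb arrays, the difference was 0.03. It was -0.61 among the arrays of wider range and 0.01 between those of narrower range, and 13 of 22 alternative settings kept the call.

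White and brown adipocyte markers were called lower in hindlimb muscles (means -0.75 and -0.76, adjusted p = 0.00544 and 0.0297; adjusted p = 0.602 for both with an estimated correlation). The trapezius array set both, with Ucp1, the uncoupling protein of brown fat, at 9.36 there and at most 5.10 elsewhere, and a white adipocyte mean of 8.0 against 6.05 in supraspinatus and 5.76 in triceps. Without trapezius the differences were -0.05 and -0.18, and without triceps -1.17 and -1.22, and the brown adipocyte call was kept in 13 of 22 alternative settings. Among the arrays of wider range they were -1.19 and -1.01, and between those of narrower range 0.12 and -0.05. Myeloid markers (10 of 12 negative, mean -0.22, adjusted p = 0.00706) and atrophy genes (mean -0.27, adjusted p = 0.0436) were also called lower, with an adjusted p of 0.602 for both with an estimated correlation. For myeloid markers triceps was highest, with a mean of 4.84, and the difference was -0.05 without it and -0.35 without supraspinatus. The myeloid difference was -0.18 among the arrays of wider range and -0.43 between those of narrower range. For atrophy genes trapezius was highest, with a mean of 6.95 against 6.22 to 6.54 elsewhere, and without it the difference was -0.12. The atrophy difference was -0.30 among the arrays of wider range and -0.18 between those of narrower range, and 6 of 22 alternative settings kept the call.

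The other lists were not called. Their mean differences were 0.12 for head patterning, 0.17 for developmental fibre, 0.47 for slow fibre, -0.16 for glycolysis, 0.08 for neuromuscular junction and 0.00 for clock genes, and 0.09 for salivary gland, -0.03 for keratinocyte, 0.06 for lymphocyte, 0.13 for endothelial, 0.09 for smooth muscle and 0.10 for cartilage and bone markers. The slow fibre value rested on soleus, with -0.54 without it, 1.35 among the arrays of wider range and -0.35 between those of narrower range. The endothelial value was -0.09 without soleus, 0.54 among the arrays of wider range and -0.21 between those of narrower range. Matrix genes had a mean of 0.04 and a median of -0.01, and Schwann cell markers a mean of 0.01 and a median of 0.

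The third comparison set shoulder and forelimb muscles against head muscles. Hox genes of groups 5 to 8 were called higher as a group, by a mean of 0.70 on the log2 scale (adjusted p = 0.264 with an estimated correlation and 0.0581 by fry). Hoxa7 was at 4.62 ± 0.48 (SD, n = 3) against 3.39 ± 0.11 (SD, n = 2), and Hoxa5 at 3.76 ± 0.70 (SD, n = 3) against 2.24 ± 0.22 (SD, n = 2), and neither passed over all genes. White adipocyte, matrix and myeloid markers were called higher, and endothelial, respiratory chain and salivary gland genes lower, as groups. For these lists the adjusted p was 0.529 with an estimated correlation for the respiratory chain and 0.385 for each of the other 5. Hoxc10 was at 3.58 ± 0.49 against 3.18 ± 0.17, a difference of 0.41 (SE 0.33, adjusted p = 0.805).

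In the limma test 0 genes were higher and 0 lower, with 702 higher and 832 lower at an unadjusted p under 0.05, where chance gives 1109 in all. The smallest adjusted p was 0.589, shared by the leading genes. On the higher side these were Ripor2 (1.40), Mmd (1.25), Nr4a1 (1.02), Hoxa7 (1.22) and the complement gene C4b (1.90). On the lower side they were Rsad2 (-1.20), Mss51 (-4.28), Malt1 (-1.02), Defa40 (-1.23) and Bpifa2 (-1.94). Over the alternative settings Mmd ran from 0.528 to 1.375 and C4b from 1.106 to 2.303. Rsad2 ran from -1.305 to -0.652 and Mss51 from -5.763 to -2.149. Without the digastric array, 3 genes were lower and 1 was higher. The former included Mss51 and the masseter genes Klk1 and Neto2, which rested on the masseter array alone.

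Hox groups 5 to 8 had 11 of 11 positive differences (adjusted p = 8.94e-07; adjusted p = 0.264 with an estimated correlation), of which Hoxa5 (1.52), Hoxa6 (0.92) and Hoxa7 (1.22) passed when adjusted over the list alone. The mean was 0.61 among the arrays of wider range. Groups 1 to 4 were called by camera with a mean of 0.28 (adjusted p = 0.0184, and 0.385 with an estimated correlation). That mean was 0.26 among the arrays of wider range and 0.18 without masseter. Groups 9 to 13 had a mean of 0.27 and no call by camera (adjusted p = 0.0538). Their mean was 0.15 among the arrays of wider range, which leave out triceps. Every shoulder and forelimb array lay above every head array for 15 of 36 Hox genes, against 15.2% of all genes and 10% by chance. Limb patterning factors were called (mean 0.28, adjusted p = 0.0436; adjusted p = 0.385 with an estimated correlation), with Lbx1 at 1.60, the 1 member past the threshold when adjusted over the list alone. The list difference was 0.29 among the arrays of wider range, 0.13 without masseter and 0.43 without digastric, and 10 of 22 alternative settings kept the call.

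White adipocyte markers had 8 of 8 positive differences (mean 1.66, adjusted p = 6.01e-06; adjusted p = 0.385 with an estimated correlation), and Adipoq (1.95), Cidec (2.47), Retn (1.61), Car3 (2.80) and Pck1 (2.90) passed when adjusted over the list alone. The trapezius array was highest for 6 of the 8, and the mean difference was 0.96 without it and -0.06 with it counted among the head muscles. It was 2.08 among the arrays of wider range. Matrix genes had 17 of 17 positive differences (mean 0.50, adjusted p = 6.01e-06), and myeloid markers 10 of 12 (mean 0.39, adjusted p = 0.000159), with an adjusted p of 0.385 for both with an estimated correlation. Csf1r, Cd68 and Mrc1, all macrophage genes, differed by 0.93, 0.97 and 0.85. Without masseter the matrix difference was 0.29 and the myeloid difference -0.001, and without digastric the latter was 0.78. They were 0.37 and 0.22 among the arrays of wider range.

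Endothelial markers had 10 of 10 negative differences (mean -0.68, adjusted p = 4.99e-06; adjusted p = 0.385 with an estimated correlation), and -0.61 among the arrays of wider range. Respiratory chain and citrate cycle genes had 22 of 23 (mean -0.32, adjusted p = 1.62e-05; adjusted p = 0.529 with an estimated correlation), -0.21 among those arrays and -0.21 without digastric or without triceps. Salivary gland markers were called lower (mean -0.48, adjusted p = 0.0201; adjusted p = 0.385 with an estimated correlation), with Bpifa2 past the threshold when adjusted over the list alone and Klk1 at -2.54. The list difference was -0.53 among the arrays of wider range and -0.26 without masseter, and 14 of 22 alternative settings kept the call.

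The remaining lists were not called. Their mean differences were 0.04 for head patterning, 0.16 for myogenic, 0.07 for developmental fibre, 0.81 for slow fibre, 0.26 for fast fibre, 0.19 for glycolysis, -0.14 for fatty acid, -0.17 for neuromuscular junction, 0.16 for atrophy and 0.10 for clock genes, and 0.74 for brown adipocyte, 0.21 for Schwann cell, 0.14 for keratinocyte, 0.14 for lymphocyte, -0.08 for smooth muscle and 0.28 for cartilage and bone markers. Without trapezius the brown adipocyte value was 0.16, the slow fibre value 0.38 and the atrophy value 0.01. The fatty acid value was -0.46 without masseter and 0.17 without digastric, and the clock value 0.24 and -0.05. Immediate early genes had a mean of 0.15 and a median of -0.02, and tendon markers a mean of -0.11 and a median of 0.05, with means from -0.99 (without masseter) to 0.76 (without digastric).

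Single muscles had no replicate, and their levels are given as values with no test. Soleus had the most genes more than 1 log2 unit above every other array, 97. Its leading genes were Sln, the sarcolipin gene, at 8.44 against at most 4.05, and the slow sarcomere genes Myl3 (10.39 against 6.70), Tnnc1, Tnni1 and Tnnt1. Trapezius had 51 such genes, led by Ucp1, Cidea (9.22 against 5.69), Pck1, Prkar2b and Slc27a2, and masseter 33, led by Klk1, Mss51, Neto2, Phxr4 and Cyp2f2. Gastrocnemius had 32, led by Pramel22, Ifi208, Ube2dnl1, Fbxw22 and Pramel16, all at values from 2.64 to 3.96. Digastric had 20, led by Mettl21e, S100a8, Bpifa2, Kera and Lcn2. Triceps had 16, led by Ms4a4c, Siglec1, Oas1g, Ctss and Adgre1. Tibialis anterior had 7, led by Cyp4f39, Ibsp, Nr4a3, Mettl11b and Mmp13, rectus femoris 5, among them Spopfm2, Magea1 and Cstdc1, and supraspinatus 0.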

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

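The tests below on the relatives of Hoxc10 and on its difference within the wider arrays, and the test of compression as the whole cause, were chosen after the results were seen. Among the 4 hindlimb muscles, 1 array lay far from the others for 2 of the values checked, which were the levels of 25 named genes and the means of 28 lists. Chance flags about 1 in 20 of such values, or 2.6 here. The level of Car3 was 10.16 in rectus femoris against 11.27 to 11.34 in the other 3, and the mean of the fast fibre genes was 10.30 in soleus against 11.54 to 11.79.

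Hoxc10 was higher in every hindlimb array than in any other. Signal from its close relatives Hoxa10 and Hoxd10 stays open, because their own probe sets, the larger of whose differences was 0.54, lie near background, where differences can be compressed. The value range of the arrays would need the difference to vanish among the 6 arrays of wider range, where it was 4.15. Chance was not excluded for the number of genes past the threshold. The 7 arrays outside the head group have 35 splits into 4 and 3. Of these, 2, the real one included, gave at least the 1 gene of the real split. The highest other, trapezius, supraspinatus, tibialis anterior and soleus against triceps, rectus femoris and gastrocnemius, gave 2122. That split follows the value range of the arrays and points to a structure of the samples. A difference in body position stays open as the biological hypothesis, and other differences between the arrays, such as the animals they came from, were not tested.

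The arrays of triceps, rectus femoris and gastrocnemius differed from the other 6 in 1984 genes by a model term, 1404 lower and 580 higher, with 1343 of the lower ones in the brighter part of the genes tested. Compression of the value scale may account for part of this, since cyclic loess left 965 genes, of which 881 were among the 1984, a number between the outcomes set for and against it. Compression that differs between probe sets could outlast quantile normalization, which gives every array the same distribution, and stays open. Compression that depends on level alone is argued against as the whole cause, since quantile normalization left 1090 genes. Of these, 970 were among the 1984. Of 83 choices of 3 arrays the next highest gave 115, but the 3 arrays were picked from the same values for standing apart. Their rank among the choices is therefore no separate support. A lower oxidative content of these muscles was left open by the respiratory chain and citrate cycle list, at percentile 14.3 of random lists. It was the list set for this test. The slow fibre and fatty acid lists lay at percentile 0 and the fast fibre and glycolysis lists at 99.9 and 100. Those lie in the direction of that explanation, but soleus, an array of wider range, weighs on the slow fibre, fast fibre and glycolysis shifts. Its fast fibre mean was 10.30 (11.17 to 11.79 elsewhere) and its glycolysis mean 9.42 (9.86 to 10.33 elsewhere). The slow fibre mean was 9.62 in soleus, 6.97 in trapezius and from 5.06 to 5.57 in the other arrays of wider range. In those of narrower range it was 6.33 in gastrocnemius, 6.00 in triceps and 4.95 in rectus femoris. Lists of other kinds were as extreme, with myeloid markers at 100 and matrix genes at 99.9. Random lists do not share the correlation within a list, so these percentiles do not decide. Hybridisation batches are not given in the labels and were not tested.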

How the results depend on the processing

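The alternatives on the value range of the arrays were chosen after seeing the data, and the others before. Hoxc10 was the 1 gene higher in hindlimb than in shoulder and forelimb muscles under all 20 alternatives. Genes higher in hindlimb than in head muscles numbered 1 under median centring, the 6 arrays of wider range, only the 2 groups compared, value range as a term, the slow fibre score, the trapezius with the head muscles, and trend with robust fit, Hoxc10 in each. The slow fibre score gave 2 lower genes, Myom3 and Tbc1d4. Leaving out 1 array gave from 0 (without masseter) to 11 (without soleus) higher and from 0 to 8 (without soleus) lower genes, and for shoulder and forelimb against head muscles from 0 to 1 higher and from 0 to 3 lower genes (both without digastric, where the lone head array is assumed to vary like the other groups). The cause was not tested. No list was called with an estimated correlation (0 in each comparison), and fry called 4, 0 and 0. For hindlimb against shoulder and forelimb muscles, 7 lists were called in the 6 arrays of wider range, 5 with the trapezius among the head muscles, and from 5 (without trapezius) to 12 with 1 array left out. Hox shifts whose call ended, with the same value under a different test, were 0.82 and 0.84 (groups 5 to 8 and 9 to 13, hindlimb against head, estimated correlation), 0.57 (9 to 13, hindlimb against shoulder and forelimb, estimated correlation and fry), and 0.70 and 0.28 (5 to 8 and 1 to 4, shoulder and forelimb against head, estimated correlation and fry). Groups 1 to 4 also lost the call with the dim filter (0.39, on fewer genes), with the trapezius among the head muscles (0.15) and without masseter (0.18). They kept it in the other 8 fits with 1 array left out (up to 0.39).

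Reversed signs were head patterning at -0.05 and respiratory chain genes at 0.032 (hindlimb against shoulder and forelimb) in the 6 arrays of wider range, and white adipocyte markers at -0.11 and -0.059 (hindlimb, and shoulder and forelimb, against head) with the trapezius among the head muscles. With 1 array left out, fast fibre genes ran from -0.47 to 0.031 (hindlimb against shoulder and forelimb), myeloid markers from -0.001 to 0.78 (shoulder and forelimb against head) and tendon markers from -0.18 to 1.58 (hindlimb against head). Of named gene values 571 were unaffected in direction and side of the threshold, 16 lost and 5 gained it. Most named values had not passed in the main fit, so that they had no call to lose and mostly count as unaffected. Only Hoxc10 in both hindlimb comparisons and Nr4a1 in hindlimb against head muscles had a call to lose. Nr4a1 kept its call under 5 of 20 settings. For lists the counts were 540 unaffected, 157 lost and 7 reversed. No scaling moved the median gene by over 0.09. No paired analysis was possible because each muscle has 1 array and the labels name no animal. Signal near background limits the Hox values, and the number of arrays limits all.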

Other observations

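The genes and muscles described here were picked after the results were seen, and no test was added for them. All 15 slow fibre genes were highest in soleus, 14 of them by more than 1 log2 unit, and Myh7, the slow myosin heavy chain gene, was at 11.62 there, 8.64 in trapezius, 8.53 in gastrocnemius, 7.66 in triceps and from 3.68 to 5.49 in the other 5. Of the 23 genes of the respiratory chain and citrate cycle, 16 were highest in digastric. Of 12 myeloid markers, 8 were highest in triceps, where Siglec1 was at 5.60 and Oas1g at 3.58, an interferon-induced gene. Of the 8 measured white adipocyte markers 6 were highest in trapezius, with Pck1 at 9.23 and Cidec at 8.32, and so were 6 of 9 brown adipocyte markers, with Ucp1 at 9.36. Of 10 tendon markers, 6 were highest in soleus. Myh8, the neonatal myosin heavy chain gene, was at 6.79 in masseter and from 3.83 to 5.56 elsewhere on the brighter of its 2 probe sets, and the difference of hindlimb from head muscles was -1.18 on this probe set and -3.91 on the other.

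Mstn, which encodes the growth inhibitor myostatin, was at 1.56 in soleus. Lbx1 was lower in both head arrays (3.71 in masseter and 4.83 in digastric) than in the other 7 (from 5.47 to 6.68), and Tbx15 was higher in both (9.30 and 9.22) than in the other 7 (from 7.36 to 8.96). Among the Hox genes, Hoxa5 was highest in supraspinatus (4.35) and trapezius (3.93), and Hoxa9 was at 2.72 in trapezius, near the head arrays (2.60 and 2.64), and from 3.41 to 4.29 in the 6 others.

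The 17824 probe sets without a gene or with several genes gave 0 past the threshold in any of the 3 comparisons by limma. At an unadjusted p under 0.05 there were 1361, 719 and 1015, with smallest adjusted p of 0.187, 0.722 and 0.155.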
